A study of Medicago truncatula with 2 samples.

How the data were processed

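The 2 libraries, MtNIN and INPUT100, were each deposited as 1 peak list in narrowPeak layout, so peaks were called per library and not pooled. Per the labels' protocols, DNA from inoculated roots was sonicated to about 250 bp, incubated with HaloTag-MtNIN made in vitro, or kept as input diluted 100 times, and sequenced. The submitters' processing notes name fastp 0.12.4, Bowtie2 2.3.4.1, SAMtools, Picard, MACS2 2.2.7.1 and ChIPseeker 1.36.0. Which tool did which step, the parameters, the genome build and whether INPUT100 served as a control are not given in the sources used here.

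The deposited fold per peak is the authors' ratio of the summit pileup plus 1 to the caller's local background plus 1. The deposited −log10 p and −log10 q values belong to the same summit, the lowest −log10 q being 1.31 in the MtNIN list and 1.38 in the INPUT100 list, just above that of q = 0.05. The deposited score is the integer part of 10 times −log10 q and was not used further. Fold and −log10 q were used only to describe, rank and filter peaks within a list. All coordinates are given as in the files, counted from 1, with the start shifted from the files' count from 0.

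From fold and −log10 p together the summit pileup and the local background were solved for each peak, under the caller's Poisson model. All pileups of both lists came out whole within 0.01, and 100% of 4500 simulated peaks were recovered when the solver was tested on simulated data. The lowest background in each list was taken as the genome-wide background. At peaks with a pileup below 100, the other background values below 12 fragments lay on even steps, within 0.1 of a step. This held for 99.9% of 5338 values in MtNIN and 100% of 14 in INPUT100. A step was taken as the fragment length over 20000, the spacing a 10 kb background counted from the library's own fragments gives. The fragment length was fitted to these values, near the narrowest peak width of each list, so that most lay on a step. The fit gave 267.6 bp for MtNIN and 233 bp for INPUT100. With such a background fold cannot exceed 37.4 in MtNIN and 42.9 in INPUT100, so strong peaks were ranked by pileup. Without read totals, the precision of a pileup is its counting error. PCR copies are not independent molecules, and intervals cover counting error only. Pileup ratios between the libraries were scaled by the ratio of genome-wide backgrounds, 1.07, with exact binomial intervals.

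Peaks were compared by overlap of at least 1 bp, beside 1000 random placements of the MtNIN peaks within each sequence. No genome sequence was used here. Genes came from a table of 39590 RefSeq genes of the assembly MtrunA17r5.0-ANR, without strand, description or exon structure. The files' sequence names carry the MtrunA17 prefix but state no build, so no coordinate of the table is printed. To see how far the lncRNA and snoRNA counts depend on exact position, all summits were moved along the chromosomes. The number of lncRNA genes with a summit within 300 bp was 199 unmoved, 26 and 33 after moves of 500 bp, 59 and 72 after moves of 1000 bp and 30 and 33 after moves of 5000 bp. The number of 107 bp snoRNA genes with a summit at 4000 to below 4100 bp was 41 unmoved and between 0 and 2 after moves of 500, 1000 or 5000 bp. The moves exclude no small offset, and gene distances assume that table and files share coordinates.

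The design fixed before the data were examined used promoters of 2000 bp, exon classes, distance to the transcription start, the NIN-type half-site, 6-mers and 24 gene lists taken from gene descriptions. None of these could be run without strand, sequence or descriptions. In their place a summit was counted as inside a coding gene or within 2000 bp of either edge, beside 1000 random placements of the summits, with exact binomial 95% intervals. Gene lists were compared with all other coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Genes were named by a rule fixed beforehand, adapted to this window: members of the curated symbiosis list with a summit and a core set with or without one, the genes at the 10 gene-associated peaks of highest fold, and the 5 INPUT100 peaks of highest fold. The part of the rule that leaves out undescribed genes could not be applied. The 77 genes with a literature name, the lncRNA genes and the snoRNA spacings were added after the data were seen. Noncoding classes of 1 biotype and length with at least 20 copies were scanned for summits in bins of 100 bp up to 10 kb by a one-sided exact Poisson test against 100 random placements.

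Counts of genes and overlaps were tested on simulated data and differed from a brute-force count in 0 cases among 960 simulated genes. A spacing planted at 40 simulated features gave 43 in its bin and at most 7 in any other, and a planted odds ratio of 4 was returned as 4.31. Alternatives were stricter peak thresholds, other overlap rules, windows of 1000, 3000 and 5000 bp and leaving out peaks that overlap an INPUT100 peak. Added after the data were seen were a window of 500 bp, shifting each summit by 5 to 50 kb, a pileup of at least 100, leaving out peaks linked to snoRNA or lncRNA genes, 200 and 500 bp lncRNA edge windows, scaling by estimated fragments, pileup ratios only at summits within 100 bp, and 10000 random lists matched on gene length. The mitochondrial and unplaced sequences were left out of gene comparisons. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.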

Results

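DNA affinity purification sequencing (DAP-seq) incubates fragmented genomic DNA with a transcription factor made in vitro and sequences the fragments the protein retains. Here the protein was HaloTag-fused MtNIN, the Medicago truncatula NODULE INCEPTION protein, an RWP-RK transcription factor required for nodule formation. The DNA came from Medicago roots 14 days after inoculation with Sinorhizobium meliloti 1021 and had been sonicated to about 250 bp. The series holds 2 libraries, 1 of fragments retained with HaloTag-MtNIN and 1 of the input DNA library diluted 100 times (INPUT100), the background control. Neither used the HaloTag alone, so unspecific retention cannot be told apart from binding by MtNIN. There was 1 sample per group, so no difference between the libraries has a replicate check, and every interval and every comparison with random placements describes these 2 libraries only and covers counting error or position. Read totals were not given in the sources used here. The genome-wide background at which peaks were called was 5.30 overlapping fragments in MtNIN and 4.97 in INPUT100, which puts the number of MtNIN fragments at 0.928 times that of INPUT100 if both were called with the same genome size setting. INPUT100 was therefore not the shallower library under that setting.

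The first comparison sets the MtNIN peaks beside the peaks of the input DNA. Background values in each list lay on the steps of a background counted from that library's own fragments, at a fragment length fitted to them. A MtNIN peak is therefore not by itself an enrichment over the input. MtNIN had 8063 peaks, of which 7946 lay on chromosomes 1 to 8, 59 on unplaced sequences and 58 on the mitochondrial genome. INPUT100 had 81 peaks, 42 of them on chromosomes 1 to 8, 6 on unplaced sequences and 33 on the mitochondrial genome. On chromosomes 1 to 8 this was 18.7 MtNIN peaks per Mb (95% exact Poisson interval 18.3 to 19.1) against 0.0986 per Mb for INPUT100 (0.0711 to 0.133). MtNIN density differed little between chromosomes, from 17.5 peaks per Mb on chromosome 6 (16.3 to 18.8) to 19.8 on chromosome 7 (18.6 to 21.0). The median MtNIN peak was 356 bp wide, with a deposited fold enrichment at its summit of 4.90 and a summit pileup of 34 fragments (quartiles 23 and 57). A summit pileup of at least 100 fragments was reached by 1013 MtNIN peaks (12.6%), and 31 reached 1000. With a stricter threshold of 10 on the deposited −log10 q, 4618 MtNIN and 38 INPUT100 peaks were left.

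The strongest MtNIN peak on chromosomes 1 to 8 without an INPUT100 peak lay on chromosome 6 at 39736453 to 39736998, with a summit pileup of 2340 fragments and a fold of 33.9. The next lay on chromosome 8 at 9803832 to 9804385, with 2328 fragments and a fold of 34.0. Both were far from annotated coding genes, 5930 bp from LOC25497370 and 7850 bp from LOC25500670. Among MtNIN peaks in or within 2000 bp of a coding gene, the highest fold, 32.9 with 617 fragments, lay inside LOC120576110 on chromosome 6 (36938737 to 36939251). It was followed by peaks 518 bp from LOC25489538 on chromosome 3 (38685314 to 38685861, 1556 fragments), 1707 bp from LOC25497844 on chromosome 7 (10680322 to 10680860, 1596 fragments) and inside LOC11439136 on chromosome 4 (52571710 to 52572210, 1479 fragments). The other members of the 10 with the highest fold were LOC11442228, LOC11440494, LOC11434383, LOC11421756, LOC11444544 and LOC25480382, with 1058 to 1312 fragments. None of the 10 had an INPUT100 peak, but only 26 of the 7946 MtNIN peaks on chromosomes 1 to 8 overlapped an INPUT100 peak at all. The gene table used here gives no description for the genes at the 10 peaks. Fold levelled off among strong peaks, with a median of 24.0 for the 165 peaks of 300 to below 600 fragments and 29.5 for the 67 peaks with 600 or more, while their median local background rose from 16.2 to 27.9 fragments.

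Most INPUT100 peaks were also in the MtNIN list. Of the 81 INPUT100 peaks, 61 (75.3%, exact binomial 95% interval 64.5 to 84.2%) overlapped a MtNIN peak by at least 1 bp, against a mean of 11.6 (range 4 to 20) when the MtNIN peaks were placed at random 1000 times. On chromosomes 1 to 8 the overlap was 28 of 42 (66.7%, 50.5 to 80.4%), against a mean of 0.72. In the other direction, 58 of the 8063 MtNIN peaks (0.719%, 0.547 to 0.929%) overlapped an INPUT100 peak. At the 28 shared loci on chromosomes 1 to 8, which hold 26 MtNIN peaks, the median MtNIN over INPUT100 summit pileup was 0.942 after scaling by the genome-wide background (quartiles 0.764 and 1.07, range 0.533 to 3.46), and 1.08 after scaling by the estimated number of fragments, so the side of 1 depended on the scaling. The ratio sets the summit of each library against the other, and the 2 summits lay within 100 bp of each other at 16 of the 28 loci, where the median was 0.839, and up to 2639 bp apart at the others. With the first scaling the counting interval of the ratio included 1 at 19 of the 28, lay above 1 at 5 and below 1 at 4. With only MtNIN peaks of −log10 q of at least 10, the shared percentage on chromosomes 1 to 8 was 45.2%.

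Of the 5 INPUT100 peaks with the highest fold, 3 lay in 1 stretch of chromosome 5. The highest, 23825340 to 23825719, had a fold of 39.4 and 1217 fragments in INPUT100 and 1213 fragments in MtNIN. The second, 23810128 to 23810844, overlaps the ribosomal RNA gene LOC112418329 and had 7394 fragments in INPUT100 and 6074 in MtNIN. The fourth, 23802181 to 23804220, had 2038 and 3133 fragments. The fifth lay on an unplaced sequence, with 148 fragments in INPUT100. The third, on chromosome 2 at 36443767 to 36444008, overlaps the coding gene LOC25487128 and had no MtNIN peak. In INPUT100 it had 1232 fragments and a fold of 35.2.

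**Figure D1:**
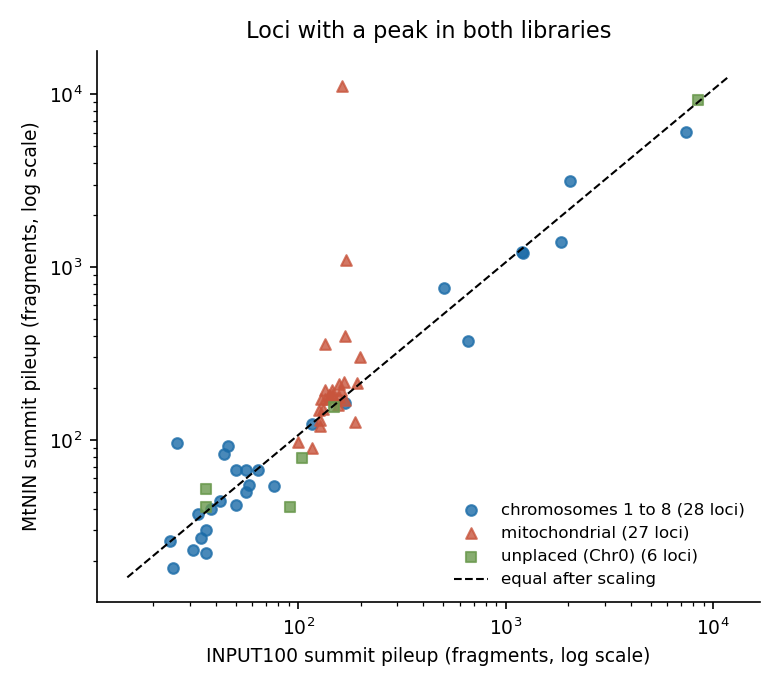
Summit pileup in fragments of the 61 loci with a peak in both libraries, INPUT100 on the x axis and MtNIN on the y axis, both on log scales. Points are single loci by sequence class, and the dashed line marks equal height after scaling by the genome-wide background. The 28 loci of chromosomes 1 to 8 lie on both sides of the line with a median ratio of 0.942, and the highest mitochondrial locus, with 11206 MtNIN fragments, lies far above it.

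The second comparison asks which genes lie at MtNIN peaks. Over all coding genes MtNIN summits were placed nearly as random positions are. Of the 7946 summits on chromosomes 1 to 8, 29.1% (28.1 to 30.1%) lay inside a coding gene against 30.6% for random placements, 23.8% (22.9 to 24.8%) lay outside but within 2000 bp against 22.6%, and 47.1% (46.0 to 48.2%) lay farther away against 46.8%. Differences of this size inside genes were rare by chance, with 3 of 1000 placements as low, and the same held near genes, with 4 of 1000 as high. Neither held throughout: with MtNIN peaks of −log10 q of at least 10 the difference near genes turned from 1.19 to -0.262 percentage points, and 70 of 1000 placements were as low inside genes. Inside genes, 72 of 1000 were as low with a pileup of at least 100, where fewer peaks gave a larger difference of -2.22 points. Without the peaks linked to lncRNA and snoRNA genes, 156 of 1000 were as low, and the difference shrank from -1.47 to -0.530 points. Near genes, leaving out the linked peaks gave a larger excess of 1.83 points, with 0 of 1000 placements as high. The linked peaks were picked by their position outside noncoding genes. Leaving them out can by itself shift the shares in and near coding genes, so this setting does not decide either result. A summit lay in or within 2000 bp of 4496 of the 31728 coding genes, against a mean of 4397 (range 4239 to 4556) for random placements. Stronger peaks did not lie in or near genes more often. The share inside coding genes ranged from 26.3% to 32.5% over 10 equal classes of summit pileup and was 28.6% (25.4 to 31.8%) in the strongest class. Inside or within 2000 bp, the share ranged from 56.9% (53.4 to 60.4%) in class 5 to 49.3% (45.8 to 52.8%) in class 8. It was 52.7% (49.2 to 56.2%) in the strongest class. For INPUT100, 12 of 42 summits (28.6%, 15.7 to 44.6%) lay inside coding genes.

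**Figure D2:**
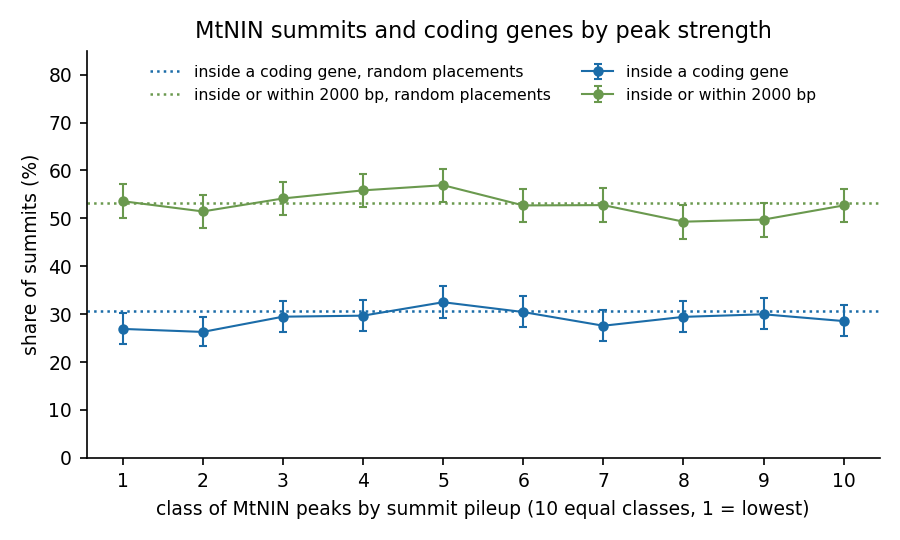
Share of MtNIN summits on chromosomes 1 to 8 that lie inside a coding gene (blue) or inside or within 2000 bp of one (green), in percent, in 10 equal classes of summit pileup from lowest to highest. Bars are exact binomial 95% intervals and dotted lines the mean of 1000 random placements. The share inside genes stays between 26.3% and 32.5%, close to the 30.6% of random placements. The share inside or within 2000 bp lies between 49.3% and 56.9%.

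Of the 41 symbiosis genes listed before the data were examined, 13 are named in the gene table, and 4 of these 13 had a MtNIN summit in or within 2000 bp. The strongest of the 4 was at ERN1, a transcription factor gene needed for rhizobial infection, where the summit lay 114 bp from the gene (chromosome 7, 40036716 to 40037103, 54 fragments, fold 6.92, −log10 q 26.8). VPY, which encodes vapyrin, needed for infection by rhizobia and mycorrhizal fungi, had a summit at 706 bp (chromosome 6, 10273065 to 10273376, 30 fragments, fold 4.92). PUB1, a U-box ubiquitin ligase gene, had one at 972 bp (chromosome 5, 37016986 to 37017322, 27 fragments, fold 3.95). NSP2, a GRAS transcription factor gene of Nod factor signalling, had one at 1037 bp (chromosome 3, 36217193 to 36217605, 15 fragments, fold 2.48, −log10 q 1.75). ENOD11, DMI3, ERN2, IPD3, NOOT1, NOOT2 and NSP1 had no summit within 5000 bp, while the nearest summits to NFP and SUNN lay 2176 and 4488 bp away. The list's share of 30.8% (9.09 to 61.4%) against 14.2% of other coding genes did not pass Fisher's exact test, two-sided (odds ratio 2.69, p = 0.10, Benjamini-Hochberg adjusted p = 0.102 over 2 lists). With a window of 500 bp the odds ratio was 0.853, with ERN1 as the 1 gene left. NIN itself, NF-YA1, NPL, CRE1, RPG, LBD16, CLE13 and NF-YA2 are not named in the table and were not analysed here.

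A wider group of 77 coding genes carries a name from the literature in the table, a group formed after the data were seen and including the 13. Of these, 16 (20.8%, 12.4 to 31.5%) had a MtNIN summit in or within 2000 bp, against 14.2% of other coding genes (odds ratio 1.59, Fisher's exact test p = 0.102, adjusted p = 0.102). The strongest was GLB1-1, a haemoglobin gene, with 746 fragments and a fold of 24.5 at a summit inside the gene (chromosome 4, 33989464 to 33989985), the summit ranking 58 by pileup among all MtNIN peaks. LB1, a leghemoglobin gene, whose product carries oxygen in nodules, had a summit 119 bp away with 209 fragments and a fold of 21.0 (chromosome 1, 2110478 to 2110950). LB6, also a leghemoglobin gene, had one 167 bp away with 29 fragments and a fold of 4.11 (chromosome 5, 29186938 to 29187213). CCS52, a cell cycle regulator gene needed for endoreduplication in nodules, had 48 fragments at 329 bp (chromosome 4, 50436020 to 50436373), and rip1, a peroxidase gene induced by rhizobia, had 46 fragments at 13 bp (chromosome 5, 33093030 to 33093455). The lectin genes Lec5 and Lec11 had 97 and 68 fragments, at 1355 bp and inside the gene. The remaining 5 were AIH, KPI106, MtCASP4, MtRBP1 and TPS4, with 19 to 59 fragments. INPUT100 had no summit in or within 2000 bp of any of the 77 genes. This does not set them apart, since only 14 of 31651 other coding genes had an INPUT100 summit.

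Long noncoding RNA (lncRNA) genes stood apart from coding genes. A MtNIN summit lay in or within 2000 bp of 498 of 2561 lncRNA genes (19.4%) against a mean of 284 (range 232 to 351) for random placements, and most of the excess lay just outside the gene. Within 300 bp of either edge, outside the gene, 199 lncRNA genes (7.77%, 6.76 to 8.88%) had a summit, against a mean of 28.3 and at most 45 in 1000 placements. A smaller excess lay farther out, with 212 genes with a summit 301 to 2000 bp from an edge against a mean of 157 (range 116 to 198). Among length classes the share within 300 bp was highest in 1 of the shorter ones, with 91 of 452 genes of 400 to below 700 bp (20.1%, 16.5 to 24.1%) against a mean of 5, followed by 52 of 706 genes of 700 to below 1500 bp (7.37%) and 54 of 1356 longer ones (3.98%). Only 47 lncRNA genes were below 400 bp, and 2 of them (4.26%, 0.520 to 14.5%) had a summit, which 99 of 1000 placements matched or exceeded. Coding genes of 400 to below 700 bp showed none of it, with 14 of 1326 (1.06%, 0.578 to 1.77%) against a mean of 14.9. Over all coding genes 379 (1.19%) had a summit within 300 bp against a mean of 354, with 92 of 1000 placements as high. Those of 1500 bp or more had 313 of 25133 (1.25%) against a mean of 280, with 33 of 1000 as high. Pseudogenes had 11 of 1562 (0.704%) against a mean of 17.3. The 198 MtNIN peaks involved lay on all 8 chromosomes at a median of 110 bp from the gene (quartiles 67.5 and 173). They had a median pileup of 40 fragments against 34 for other peaks on chromosomes 1 to 8, and none overlapped an INPUT100 peak. Some lay close together, as those starting at 32207787, 32218040 and 32225358 on chromosome 3. Genes and peaks are therefore not independent replicates, and the intervals do not cover this. Inside lncRNA genes there was no excess, with 112 summits against a mean of 113. The strongest were beside LOC11416593 (95 bp away, 1880 fragments, chromosome 5, 32093658 to 32094206) and LOC11415689 (151 bp away, 827 fragments, chromosome 5, 32082455 to 32082992), both chosen after their values were seen, as was the gene class.

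**Figure D3:**
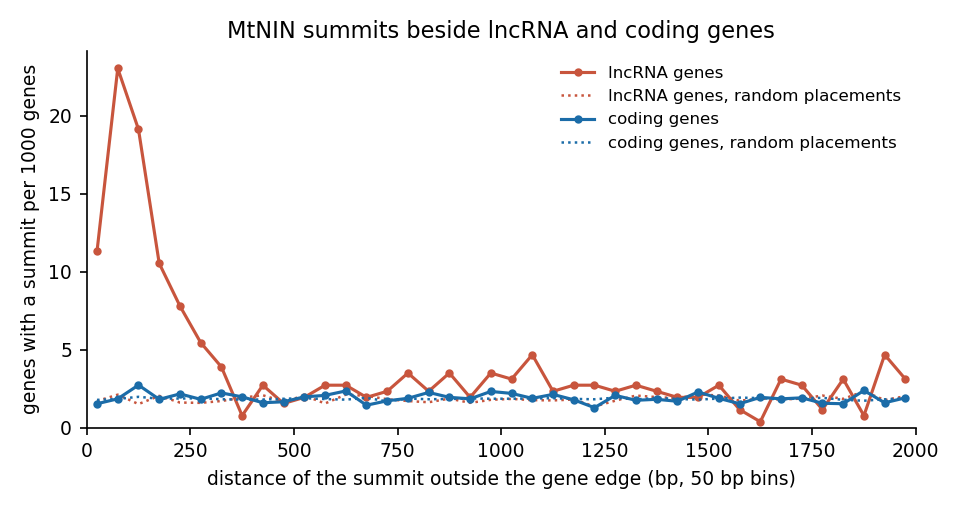
Number of genes with a MtNIN summit per 1000 genes, by distance of the summit outside the nearer gene edge in bins of 50 bp, for 2561 lncRNA genes (red) and 31728 coding genes (blue). Dotted lines are the means of random placements. lncRNA genes peak at 23.0 per 1000 in the bin from 50 bp. Coding genes reach at most 2.74 per 1000, in the bin from 100 bp, against 1.99 for random placements.

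Small nucleolar RNA (snoRNA) genes of 107 bp, of which the table has 566 on chromosomes 1 to 8, had MtNIN summits at fixed distances. At 4000 to below 4100 bp from the gene edge, 41 copies had a summit against 2.07 expected from random placements (exact Poisson test, one-sided, p = 3.43e-38, adjusted p = 6.17e-35 over 1800 bins of 18 noncoding classes). At 1600 to below 1700 bp there were 38 (exact Poisson test, adjusted p = 2.24e-31) and at 1500 to below 1600 bp 20 (adjusted p = 7.06e-11), and these 3 bins were the ones that passed. Bins and copies are not independent replicates. The 41 summits lay at a median of 4049 bp with an SD of 17.2 bp, on all 8 chromosomes, 20 to the left and 21 to the right of the gene. They were strong, with a median of 238 fragments (quartiles 99 and 500) against 34 at other peaks of chromosomes 1 to 8, and 9 were among the 100 strongest there. The highest were 997 fragments beside LOC120577261 on chromosome 7 (16773779 to 16774236) and 939 beside LOC120578797 on chromosome 2 (21014237 to 21014722). The 58 summits at 1500 to below 1700 bp had a median of 59.5 fragments. No copy had summits at both distances, and 0 of the 99 peaks overlapped an INPUT100 peak. Ribosomal RNA genes of 117 to 119 bp had a MtNIN summit in or within 2000 bp of 0 of 1367 genes, against a mean of 96.2 (range 11 to 231) for random placements. INPUT100 also had 0, which says little because it had only 42 summits on chromosomes 1 to 8.

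**Figure D4:**
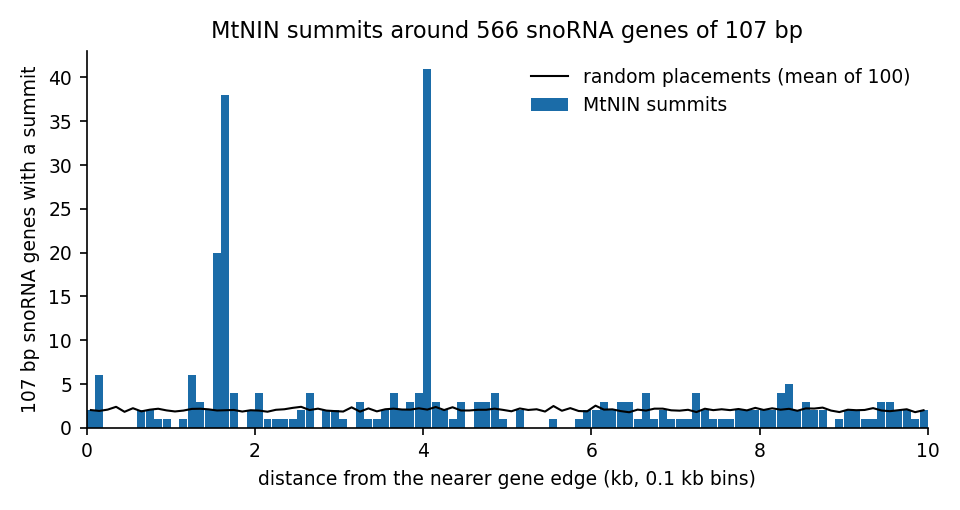
Number of the 566 snoRNA genes of 107 bp with a MtNIN summit, by distance of the summit from the nearer gene edge in kb in bins of 0.1 kb. Bars are MtNIN summits and the line is the mean of 100 random placements. Bars of 38 and 41 copies stand in the bins from 1600 and 4000 bp, against 2.07 expected.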

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

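The tests of explanations in this part, and the pileup ratio they use, were chosen after the results were seen. The mitochondrial genome entered none of the gene comparisons, and the 4 strongest MtNIN peaks there stood far above the highest INPUT100 pileup on the same sequence, 199 fragments. They had 11206 fragments (154220 to 154844), 2625 (219707 to 220208), 2254 (225642 to 226226) and 1098 (213969 to 214517). At the first, the MtNIN over INPUT100 ratio was 64.5 after scaling by the genome-wide background.

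Peaks shared by both libraries raise the question whether the input was subtracted. If INPUT100 had been the control in MtNIN peak calling, the MtNIN local background would have to reach the scaled INPUT100 pileup, but it was below it at 28 of the 28 shared loci on chromosomes 1 to 8, including all 16 with summits within 100 bp, which argues against such a control. Regions where fragments pile up in any library from this DNA stay open as an explanation: the median pileup ratio was 0.942, or 1.08 scaled by estimated fragments, but single loci went both ways, with an interval that includes 1 at 19 of the 28. The ratio leaves out INPUT100 peaks without a MtNIN peak, since 28 of 42 on chromosomes 1 to 8 were shared. Of the 10 with at least 100 fragments, 9 were shared, but the chromosome 2 peak with 1232 fragments was not. Whether MtNIN adds to or takes from such a pile-up cannot be told apart from differences between 2 single libraries. No biological explanation was tested.

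Fixed distances to 107 bp snoRNA genes could arise from copies of a repeat that carry the snoRNA-like stretch and a sequence retained by MtNIN. This was not tested, and no copy had summits at both distances, so a repeat with both sites is not shown. The copies were grouped by biotype and length, without their sequence. A pile-up of like height already present in the input is argued against, since 0 of the 99 linked MtNIN peaks had an INPUT100 peak. Of the 99, 43 had at least 100 fragments, and INPUT100 peaks went down to 18. The 0 does not set these peaks apart, since only 26 of all 7946 MtNIN peaks on chromosomes 1 to 8 overlapped an INPUT100 peak. A rise in the input too small to be called is not excluded. Chance positions are argued against by the scan itself, with an adjusted p of 6.17e-35 over 1800 bins at 4000 to below 4100 bp (exact Poisson test). The 41 copies there, beside at most 6 at any distance outside the called bins, restate that call. They are not a second test, since the bin was picked by its count. Reads shared between near-identical copies stay open: 17.5% of the copies had a linked summit, and how far reads from bound copies reached others cannot be told apart without mapping qualities or sequence. No biological explanation was tested.

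Summits beside lncRNA genes, most often those of 400 to below 700 bp, might likewise be a feature of the input DNA or of short genes in general. A pile-up of like height in the input is argued against by 0 of 198 linked peaks with an INPUT100 peak, 31 of the 198 having at least 100 fragments. The 0 does not set these peaks apart, since only 26 of all 7946 MtNIN peaks on chromosomes 1 to 8 overlapped an INPUT100 peak. A rise in the input too small to be called is not excluded. Short genes in general are argued against by the 1.06% of coding genes of 400 to below 700 bp with a summit within 300 bp, below the interval at lncRNA genes of that length. That these lncRNA genes share a promoter-like or repeat-derived sequence is an open candidate explanation, which needs sequence and strand. Reads shared between copies were not tested here.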

How the results depend on the processing

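Of 57 alternatives, 30 planned and 27 chosen after seeing the data, 38 left the result alike in direction and call or within its limits. For counts those limits were wide. Drops from 8063 to 6326 MtNIN peaks and from 81 to 58 INPUT100 peaks at −log10 q of at least 5 counted as alike. For the 2 gene lists, alike meant the same direction and no call in either setting. Stricter thresholds lowered peak counts by construction, to 4618 and 38 at −log10 q of at least 10 and to 3885 and 23 at a fold of at least 5 in MtNIN and INPUT100. The shared percentage of INPUT100 peaks went from 75.3% to 64.2% with at least 50% of the INPUT100 peak covered and to 60.5% with MtNIN peaks of −log10 q of at least 10, which gave 45.2% on chromosomes 1 to 8. Scaling by estimated fragments gave a median pileup ratio of 1.08. The deficit inside coding genes was no longer called with −log10 q of at least 10 (-0.996 points). A pileup of at least 100 gave -2.22 points, also not called, and both settings left fewer peaks. Without peaks linked to snoRNA or lncRNA genes the deficit was -0.530 points, not called, but those peaks were picked by their position. The excess near genes turned to -0.262 points with −log10 q of at least 10. It was 0.816 points, not called, with a pileup of at least 100, and 1.83 points, called, without the linked peaks. The cause was not tested. Genes with a summit numbered 7444 with 5000 bp, 2825 with 500 bp and 2585 with −log10 q of at least 10, by the size of the window or peak set. For symbiosis genes the odds ratio turned to 0.853 at 500 bp, where 1 of 13 genes had a summit; no alternative brought either list past the threshold. Against random lists matched on gene length, the 2 lists stood at percentiles 96.1 and 97.2. With a pileup of at least 100, lncRNA genes with a summit beside them fell to 31 and snoRNA copies with one at 1500 to below 1700 bp to 13, both above every placement drawn. Not run for lack of sequence, strand or description: placement avoiding runs of N, the window around the transcription start, lists matched on GC content, and all half-site and 6-mer alternatives. No paired analysis was possible because each group has 1 sample. The effect of depth was not tested; the lowest MtNIN pileup called was 14 fragments.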

Other observations

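The full set of MtNIN peaks showed no detectable relation to coding gene number along the chromosomes. Over 420 windows of 1 Mb, with 6 to 115 coding genes each, Spearman's rho of peak number against gene number was -0.021. It lay inside the range of -0.052 to 0.106 that held 95% of rho values when peak counts were shifted along each chromosome. Pearson's r was -0.029 and was not set against shifted values. For the peaks with a pileup of at least 100, rho was -0.114 and r was -0.156, and rho lay just below the shifted range of -0.104 to 0.132, with 20 of 1000 shifts as low and 86 as far from 0 in either direction. In 5 equal classes of 84 windows from fewest to most genes, the mean number of such peaks was 2.77, 2.02, 2.31, 2.08 and 1.95; differences between classes were not tested. This second relation was 1 of 2 computed and was tested after its value was seen. Windows are not independent replicates. Peak number per window had a median of 18, a range of 8 to 43 and a variance of 1.18 times its mean.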
